A study of Mus musculus with 31 samples.

How the data were processed

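RNA was measured in mammary tissue, taken without lymph nodes, of mice with 0 to 4 functional Stat5a and Stat5b alleles at day 6 of pregnancy and within 12 hours of delivery. Total RNA was extracted with TRIzol and poly(A) libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. Reads were base-called with CASAVA and aligned with TopHat to the mouse build mm9, per the submitters' processing notes, which give no versions. The program that estimated FPKM, the gene annotation and any filter are not stated. The deposited values are FPKM (fragments scaled to transcript length and to the number of mapped fragments) per gene symbol, 22609 genes in each of 2 tables, with 1 column per genotype. The labels list 31 samples, so the authors pooled the samples of a genotype into a mean. The decimals bear on this: of the values of at least 1 FPKM, between 65.8% and 66.8% end in a recurring 3 or 6 in the columns with 3 listed samples, and 0% do in the columns with 2. The labels' protocol speaks of 2 mice per genotype although 3 samples per genotype are listed for day 6 of pregnancy, and this was left as it stands. Read depth is unknown, so no interval for counting error was computed.

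The planned tests could not be used. They were limma with empirical Bayes variance for each comparison, camera and fry for gene lists, an analysis with a replicate block, fits that leave out each replicate, and permutations of the samples. All of them need a value per sample, and the tables hold means. Differences are therefore described as ratios of means with no error, number of replicates or p-value, and no claim of significance is made. A seventh genotype of the design, with Stat5b knocked out and 2 Stat5a alleles, is not analysed here.

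Within each stage, the 6 columns were scaled by the median ratio to the geometric mean over genes with at least 1 FPKM in all 6 columns (11733 genes at day 6 of pregnancy and 10864 at parturition). Scaling factors ranged from 0.916 to 1.07 and from 0.794 to 1.13. Genes with at least 1 FPKM in at least 2 of 6 columns were compared, 13367 at day 6 and 13061 at parturition. The value reported is the log2 ratio of scaled FPKM + 1, and genes were counted when they differed at least 2-fold (4-fold as a second count). There were 10 comparisons per stage: each of the 5 genotypes against wild type, A against B, AB against BB, BB against B, and B and A against Null. The 2 tables were kept apart. Stages were compared only through the difference of Null and wild type within each table.

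The 19 gene lists were fixed before the data were examined: milk proteins, milk lipid synthesis, STAT5-linked signalling, cell cycle, secretory pathway and unfolded protein response, interferon response, STAT3 and involution, and markers of luminal, hormone-sensing and basal epithelium, adipocytes, brown adipocytes, skeletal muscle, fibroblasts and matrix, endothelium, macrophages, T cells, B and plasma cells, and nerve and Schwann cells. A few genes stand in 2 lists, such as Cidea in milk lipid synthesis and brown adipocytes. For each list with at least 3 measured genes the median log2 ratio was taken, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these columns. The genes named in the text followed a rule set before the data were examined and adapted to means. It takes Stat5a and Stat5b, up to 4 members per described list, and, of genes with characterised names, the 10 highest and 10 lowest for Null against wild type and the 5 highest and 5 lowest elsewhere. The largest absolute log2 ratio stood in for the smallest adjusted p, and the conditions on adjusted p and on separation of samples were dropped. For stage differences the rule takes members of the fixed lists. A few genes that the rule takes are not reported here.

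Alternatives tried were a pseudocount of 0.1, no filter on low values, and FPKM as deposited without scaling. A floor of 5 FPKM, and removal of the trend of the ratios with GC content and transcript length by lowess, were chosen after seeing the data. Length and GC came from GENCODE M21 by gene symbol, 20284 genes directly and 1925 through a synonym (98.2%), and no coordinates were used because the build differs from mm9. The calculation was tested on simulated data built on the wild-type column of each stage (13007 and 11812 genes). In the simulated Null column 200 genes were changed 4-fold, equally up and down, so a one-sided change such as that of milk genes was not simulated. The calculation recovered 100% of the changed genes with 0 unchanged genes past 2-fold, and a depth ratio of 1.3 was recovered as 1.30 at day 6 and 1.31 at parturition. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.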

Results

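Poly(A) RNA of mouse mammary tissue was sequenced at 2 stages, day 6 of pregnancy and the day of parturition (within 12 hours of delivery), in 6 genotypes that carry 0 to 4 functional copies of the adjacent genes Stat5a and Stat5b. These genes encode the transcription factors that the prolactin receptor activates in mammary epithelium. Null mice lost both genes in mammary epithelium only (Stat5ab floxed, MMTV-Cre). B mice kept a single Stat5b allele and A mice a single Stat5a allele. BB mice (Stat5a knockout) kept 2 Stat5b alleles, AB mice 1 allele of each gene, and AABB denotes wild type with 4 alleles. Comparisons of Null with B and A therefore differ in the way the genes were lost as well as in copy number. The labels list 18 samples at day 6 of pregnancy (3 per genotype) and 13 at parturition (3 for B and 2 for each other genotype). The tables hold 1 FPKM column per genotype and stage, which is the authors' mean over samples, so every value below is a mean without an SD, no difference has a replicate check, and no p-value is given. The sequencing depth is unknown, and FPKM sums per column ranged from 433958 to 528347 at day 6 of pregnancy and from 432576 to 1190590 at parturition. Levels are FPKM scaled between the columns of a stage. Ratios are log2 ratios of scaled FPKM + 1, which understate the differences of weakly expressed genes. A gene counts as higher or lower when it differs at least 2-fold on this scale. With a pseudocount of 0.1 in place of 1, the total of such genes was larger in every comparison.

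Stat5a and Stat5b themselves came first, as a check of the genotype labels. Stat5a stood at 33.6 in wild type on day 6 of pregnancy and at 70.8 at parturition. It was lowest in BB, the Stat5a knockout, at 3.67 and 4.30. In the column labelled B, which should hold no functional Stat5a allele, Stat5a was 12.5 and 8.60, above BB at both stages. In A it was 15.9 and 16.5, in AB 13.4 and 22.9, and in Null 13.6 and 6.96. Stat5b ranged from 9.04 in Null to 16.7 in wild type on day 6 and from 7.65 to 25.4 at parturition. The column labelled A, with no functional Stat5b allele, still held Stat5b at 10.6 and 10.3. A gene-level FPKM can include transcript of a disrupted allele and of stromal cells, so these levels do not measure functional copies. Stat5b in A was below its level in B (12.3 and 12.6) at both stages. Because the B column still held Stat5a transcript, and the A column Stat5b transcript, every direction given for them refers to the columns labelled B and A.

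**Figure D1:**
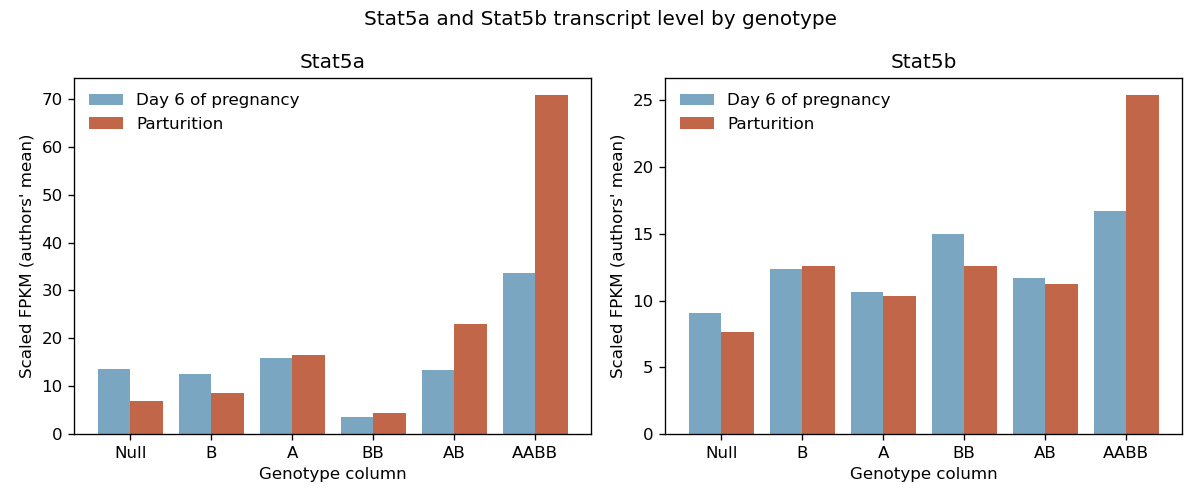
Scaled FPKM of Stat5a and Stat5b (vertical axes) in the 6 genotype columns of each stage; each bar is the authors' mean over samples and has no error bar because the files hold no replicate values. Stat5a at parturition runs from 4.30 in BB to 70.8 in AABB.

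On day 6 of pregnancy, Null glands lacked most of the early milk protein transcript seen in wild type. Csn2 (beta-casein) was 4.96 against 2959, Csn1s1 2.62 against 1148 and Csn1s2a 6.04 against 1197. Of 27 cell cycle genes 8 were lower, as were several prolactin-responsive regulators, and 8 of 18 adipocyte markers were higher. In all, 296 genes were higher and 279 lower in Null among 13367 tested. Without scaling the split was 226 and 339, so the balance of directions depended on the scaling. Of 12 measured milk protein genes, 10 were lower and 1, the antimicrobial lactoferrin gene Ltf, was higher, at 308 against 50.6. The list's median log2 ratio was −2.06, below that of each of 10000 random lists matched on expression. The cell cycle list had a median of −0.94, within 2-fold, and none of its genes was higher. Among the lower ones Ccna2 was 3.89 against 10.7, Cdk1 4.65 against 12.4 and the proliferation marker Mki67 3.16 against 8.46. In the STAT5-linked signalling list, 5 of 14 genes were lower. They included Tnfsf11, which encodes RANKL, at 7.54 against 47.5, the alveolar transcription factor Elf5 at 32.9 against 113, the feedback inhibitor Cish at 19.5 against 52.7, and Id2 at 26.9 against 69.4. Hormone-sensing epithelial markers went both ways, with Cited1 (log2 ratio −2.86) and Calca (−2.51) among 4 of 11 that were lower and 3 that were higher. Luminal markers had a median of −0.61, with Ehf (−1.78) and Muc1 (−1.73) lowest.

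Across all genes, the highest in Null on day 6 were the protease inhibitor gene Spink3 (82.5 against 1.73), the ion cotransporter gene Slc12a2 (209.8 against 18.3), Ly6d (188 against 17.6) and Syt8, Ache, Fam25c, Crym, Defb1, Cxcl17 and Cyp2e1, with log2 ratios from 2.59 to 3.22. Besides the caseins, the lowest were Wfdc12 (3.05 against 133), the Wnt agonist gene Rspo1 (3.49 against 105), the gap junction gene Gjb2, the serotonin synthesis gene Tph1, Ucp1, the butyrophilin gene Btn1a1 and Acot11. Adipocyte markers had a median of 0.98 (Adrb3 2.04, Car3 1.64). Brown adipocyte markers were 5 of 7 lower (median −1.15), with Ucp1 at 20.6 against 309. Skeletal muscle markers were 10 of 14 higher (median 1.87; Acta1 144 against 30.3). Fibroblast and matrix markers (0.00, 1 of 14 higher), endothelial (0.36), macrophage (−0.32), basal (0.28) and nerve markers (−0.13) had medians within 2-fold. So had milk lipid synthesis (−0.19), secretory pathway (−0.18), interferon response (−0.27), STAT3 and involution (0.20), T cell (0.62) and B and plasma cell genes (0.81).

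With a single allele, milk protein genes on day 6 were also below wild type, 10 of 12 in the column labelled B and 9 in the column labelled A. Csn2 was 0.102 in B and 0.707 in A, and the milk list medians against wild type were −3.26 and −3.07. Csn1s1, at 33.3 in A, was higher than in B (2.92). The mast cell protease genes Cpa3, Mcpt4 and Cma1 were among the 5 highest in both, with Cpa3 at 89.1 in B, 85.0 in A and 0.974 in wild type, Mcpt4 at 132, 128 and 3.45, and Cma1 at 124, 118 and 3.78. Among B-lymphocyte genes, Cd79a stood at 61.0, 53.5 and 1.10 and Ms4a1 at 21.9 in A against 0.137. The B-cell attractant gene Cxcl13 was 39.3 in B against 0.351. In B, 1011 genes were higher and 693 lower than in wild type, and in A 937 and 740. With the trend of the ratios with transcript length and GC content removed, these were 914 and 384 in B and 778 and 385 in A, and 949 and 838 of those genes were also 2-fold different before, so the counts of lower genes depended on that trend. B and plasma cell markers had medians of 3.88 and 3.12 (9 and 8 of 9 higher). Fibroblast and matrix markers had 1.42 and 1.38, with 9 and 8 of 14 higher (Dcn 3.06 and 3.08), macrophage markers 0.81 and 0.67, and T cell markers 1.41 and 0.43. Basal and myoepithelial markers had medians of 0.85 and 1.07 (Krt17 1.49 and 1.82). Luminal markers had medians of −0.84 and −0.93, with 7 and 8 of 18 lower, among them Spint2 (−2.21 and −2.28) and Cldn7 (−2.17 and −2.40). Skeletal muscle markers had medians of −1.60 and −0.68, and brown adipocyte markers −3.17 and −3.07. Tmem45b was 1.81 in B and 1.73 in A against 172. Wfdc12 was 1.75 in B against 133, and Ucp1 was 3.36 in A against 309. Beside these values, Null, with no allele, had Cpa3 at 3.98 and Mcpt4 at 11.4, above wild type by log2 ratios of 1.34 and 1.48 and below both B and A.

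The 2-allele genotypes BB and AB also stayed far below wild type for the early caseins on day 6. Csn2 was 2.83 in BB and 1.96 in AB, Csn1s2a 0.476 and 0.227, and Csn1s1 39.8 and 7.84. The milk list medians were −2.73 and −3.51, and Cish, at 10.3 and 19.2, was below its wild-type level of 52.7. Cell cycle genes had medians of −0.28 and −0.28, with only 2 and 1 of 27 lower, and Mki67, the lowest of them, at 1.95 and 2.08. Against wild type, 684 genes were higher and 481 lower in BB, and 906 and 670 in AB. Without scaling these splits became 571 and 664 in BB, and 675 and 997 in AB. In BB the genes farthest above wild type were Cpa3, Mcpt4, Cma1 and the mast cell tryptase gene Tpsb2 (log2 ratios 4.12 to 4.98) and the fibroblast gene Pi16, at 178 against 6.43. Null had Pi16 at 17.1, a log2 ratio of 1.29 to wild type. Fibroblast and matrix markers were 13 of 14 higher in BB and 14 in AB, with medians of 1.90 and 1.86 (Fn1 2.70 and 2.67). In AB the 5 highest were all muscle genes, Actn3, Myh4, Atp2a1, Ckm and Mybpc2, with Ckm (muscle creatine kinase) at 1328 against 18.8. The skeletal muscle median in AB was 5.36, against 0.04 in BB. Interferon response genes had a median of 0.68 in AB (Ifit1 1.29, Usp18 1.27) and −0.14 in BB. Luminal markers were −0.57 in BB and −0.99 in AB, and basal markers 0.94 in both. Brown adipocyte markers had medians of −3.76 and −2.86, macrophage markers 0.69 and 0.81 (6 and 6 of 12 higher), adipocyte markers 0.00 and 0.75, and endothelial markers 0.38 and 0.70. Gdpd3 was among the 5 lowest in both genotypes, at 0.639 and 0.553 against 61.7. Ucp1 (−6.68) and the fatty acid carrier gene Fabp3 (1.11 against 78.6) were so in BB, and the secreted mucin gene Glycam1 in AB, at 0.0247 against 81.6.

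The isoform comparisons ask whether Stat5a and Stat5b at equal copy number differ in effect, and few genes differed at 1 copy on day 6. Between the columns labelled A and B, 18 genes were higher in A and 33 lower, or 13 and 14 among genes of at least 5 FPKM in 2 or more columns and 40 and 63 with a pseudocount of 0.1. The 2 columns correlated at r = 0.995 across genes, which are not independent replicates. Samples of A and B carry tags with shared numbers, at both stages, ending in L for B and in R for A. The labels do not say whether such samples share an animal. No other genotype has tags of this form, so comparisons of A or B with the other genotypes also set differently tagged samples against each other. A likeness of the A and B columns from shared animals and one from the isoforms could not be separated. Csn1s1 was highest in A relative to B (33.3 against 2.92), with Wfdc12 (18.1 against 1.75), Tph1, Hepacam2 and Apoa2. The chemokine genes Ccl22 (0.806 against 11.5), Ccl5 (9.62 against 68.9) and Cxcl13, with Spink3 and Saa3, were lowest; Saa3 belongs to a family of similar genes and its level is uncertain. T cell markers had a median of −0.98, skeletal muscle markers one of 0.82 and milk protein genes one of 0.23, with 2 of 12 higher. Between AB and BB, 231 genes were higher in AB and 132 lower, or 135 and 94 with the floor of 5 FPKM. After Mup10, the muscle genes Actn3, Myh4, Ckm and Tnnt3 were the highest (log2 ratios 5.87 to 6.36, list median 5.49). The muscle list had a median level of 532 in AB and 12.1 in BB. At parturition these levels were 0.467 and 0.448, so the muscle difference did not recur. Luminal markers had a median of −0.46 with none past 2-fold (Krt18 −0.80). Lower in AB were 3 of 12 milk protein genes, and 4 of 19 interferon response genes were higher (median 0.62). Mup10 was 163 in AB and 0.0688 in BB, while H2-K2, Hal, H2-Q2, Ifi202b and Gchfr were each at or below 1.20 in AB and between 16.6 and 49.3 in BB. Each of the latter genes was lower in AB than in every other column, wild type and Null included. Outside AB, Gchfr was 26.9 to 49.7 and Hal 5.42 to 29.1. Mup10 was likewise lower in BB than in every other column. These ratios set a single column apart from all others and cannot be read as isoform differences alone. Mup10, H2-K2, H2-Q2 and Ifi202b have close relatives in the genome, and their levels are uncertain.

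Comparing BB with the column labelled B, 2 Stat5b alleles against 1, 8 of 9 B and plasma cell genes were lower, and 11 of 14 muscle and 5 of 14 fibroblast and matrix genes higher, in BB on day 6. Milk protein genes were 5 of 12 higher, led by Csn1s1 (39.8 against 2.92), and Glycam1 was lower (13.5 against 69.8). Tmem45b, Fcgbp, Wfdc12 and Kera were the other highest genes (log2 ratios 2.61 to 4.84). Counts were 250 higher and 613 lower, or 159 and 801 without scaling, 153 and 576 with the length and GC trend removed, and 226 and 377 with the floor of 5 FPKM. The B and plasma cell genes included Cd79a (−4.55) and Ms4a1 (−3.95), with a list median of −3.17. Mup10 and Spink3 were also among the lowest genes. Fibroblast and matrix markers had a median of 0.62 (Col1a1 2.26) and skeletal muscle markers one of 1.44. With 1 allele against none (columns labelled B and A against Null), most milk protein genes were not above Null on day 6, with 1 higher and 6 lower in B, and 4 and 6 in A. The list median was −1.51 in B and below that of each of 10000 matched random lists in both, with Ltf at 5.11 in B and 6.23 in A against 308 in Null, while Csn1s1 was higher in A (3.24). Tnfsf11 was 41.0 in B and 52.9 in A against 7.54. The STAT5-linked signalling list that holds it had medians of only −0.05 in B and 0.12 in A. These changed sign without scaling in B and with the trend removed in A. Cell cycle genes had medians of 0.35 and 0.34, with 2 of 27 higher in each, among them Mki67 at 7.74 in both against 3.16. Among the highest genes were Ifi202b, Cpa3, Retnlg and Timd4 in B, and Ifi202b, Retnlg, Cpa3, Tph1 and Mcpt4 in A. Lowest were Tmem45b and Ltf in both, the muscle genes Ckm, Pvalb and Acta1 in B, and Ly6d, Spink3 and the water channel gene Aqp5 (10.1 against 147) in A. Counts were 858 higher and 528 lower in B and 813 and 624 in A; without scaling they were 1080 and 366, and 1027 and 434. With the trend removed they were 843 and 349, and 737 and 398. Beside these stand adipocyte medians of −0.95 and −0.94, fibroblast medians of 1.35 and 1.41, and B and plasma cell medians of 2.94 and 2.54. Skeletal muscle markers had medians of −3.54 and −2.64 (13 and 12 of 14 lower), brown adipocyte markers −1.33 and −1.92, macrophage markers 1.33 and 1.20, endothelial markers −0.65 and −0.72 and basal markers 0.62 and 0.80.

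At parturition, the Null gland held almost none of the milk transcript that filled the wild-type library. The milk protein list made up 0.735% of all FPKM in Null and 65.6% in wild type. All 14 of its genes were lower, with a median log2 ratio of −8.92. Csn2 was 504 against 243805, Csn3 119 against 72859, the lactose synthase subunit gene Lalba 19.0 against 10866, and Spp1 (osteopontin) 33.5 against 32349.8. Most listed genes of milk fat synthesis and the secretory pathway were lower, and most markers of hormone-sensing epithelium, adipocytes, fibroblasts and muscle were higher. The counts were 2489 higher and 1400 lower among 13061 tested genes, of which 646 and 399 differed 4-fold; without scaling the 2-fold counts were 3741 and 783. The other lowest genes were Csn1s2b, Lao1, which encodes an amino acid oxidase (12.1 against 12068), Fabp3, the medium-chain fatty acid thioesterase gene Olah (1.10 against 1156), Glycam1, Csn1s1 and Csn1s2a. In the milk lipid synthesis list, 12 of 19 genes were lower and 2 higher. Its lowest members after Olah were Cidea (25.4 against 1828), Aldoc and Fads1. Secretory pathway and unfolded protein response genes were 12 of 20 lower (median −1.23), with the translocon gene Sec61b at 55.8 against 469.5 and the secretory regulator Xbp1 at 117 against 782. Elf5 was 66.9 against 1085 and Id2 56.0 against 346, while Bcl6 (29.9 against 3.81) and Igf1 (30.4 against 3.76) were higher. Cell cycle genes had a median of −0.81, with Mki67 at 1.86 against 26.5.

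Hormone-sensing epithelial markers were 7 of 11 higher in Null at parturition and none was lower. Foxa1, a cofactor of the oestrogen receptor, was 46.9 against 1.01 and Calca 26.4 against 1.47. Luminal markers had a median of −0.17 (0.28 without scaling), with Muc1 (−4.27) and Cd24a (−3.23) lower and Krt7 (2.65) and Kit (2.55) higher. Interferon response genes were 12 of 19 higher (median 1.13; Oasl2 2.58, Ifit3 2.04). The STAT3 and involution list went both ways, 4 higher and 6 lower of 15, with Lcn2 at 227 against 4338 and Igfbp5 at 348 against 73.8. Highest of all genes was Ido1, the tryptophan-degrading enzyme, at 69.6 against 0.180, followed by Ly6d, Atp2a1, the growth factor gene Ptn (143 against 3.14), Myh4, Foxa1, Pygm, Acta1, Tmem45b and Fcgbp. Atp2a1, Myh4 and Acta1 belong to the skeletal muscle list. Beside these groups stand medians of 3.53 for skeletal muscle markers (14 of 14 higher) and 2.56 for adipocyte markers (16 of 18; Lep 4.28, Plin1 3.91), with 2.35 for fibroblasts (14 of 14; Col1a1 3.04). Endothelial markers had 1.47 (10 of 11), nerve markers 1.59 (5 of 6) and macrophage markers 1.22 (7 of 12). Basal markers had a median of −0.43 and brown adipocyte markers one of −0.28, both above 0 without scaling (0.04 and 0.02). T cell markers, with 3 genes measured, had 0.40, and the B and plasma cell list, with 1, was not scored.

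**Figure D2:**
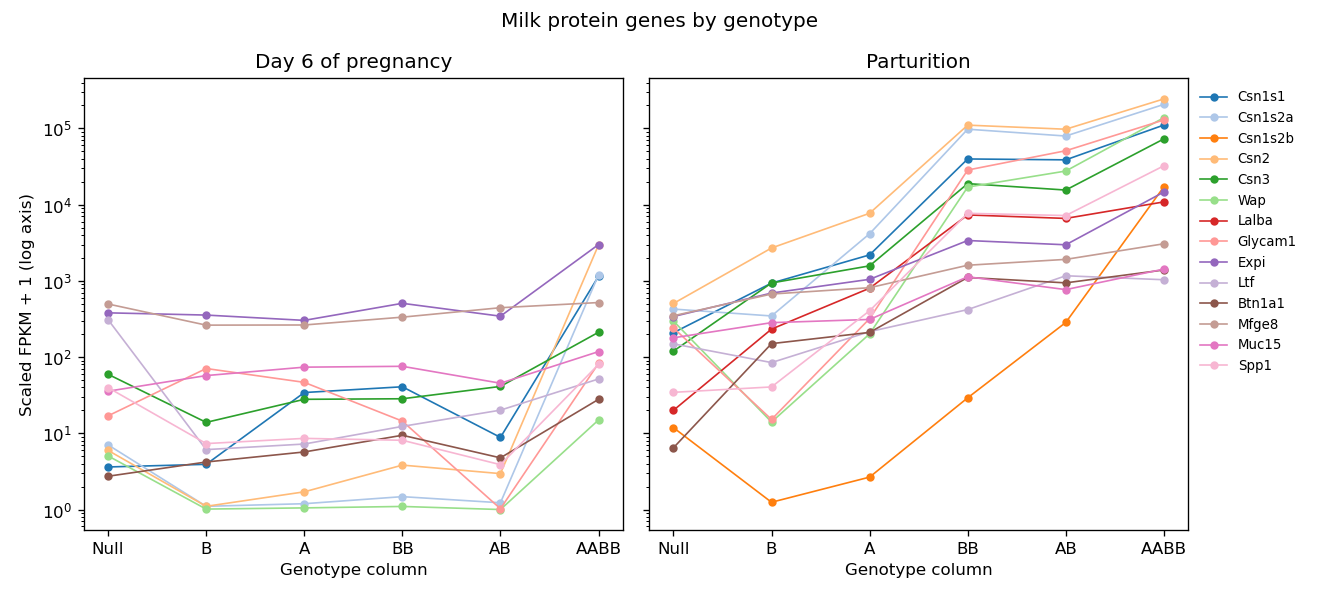
Scaled FPKM + 1 (log axis) of the milk protein genes in the 6 genotype columns, with day 6 of pregnancy on the left and parturition on the right; each point is the authors' mean over samples, and lines join the points of a gene. At parturition Csn2 runs from 504 in Null through 2698 in B and 7706 in A to 243805 in AABB.

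With 1 allele, milk transcript at parturition was far below wild type. Against Null, 6 of 14 milk protein genes were higher and 3 lower in the column labelled B, and 9 higher and 1 lower in the column labelled A. The milk list held 1.69% of FPKM in B and 4.42% in A. All 14 genes were lower than in wild type in both, with medians of −6.39 and −5.26. Csn1s2b was 0.246 in B and 1.66 in A against 17144, the whey protein gene Wap 13.1 and 201 against 138276, and Glycam1 14.2 and 319 against 129120.0. Fabp3, Spp1 in B and Cidea in A were the other lowest genes. Milk lipid genes were 16 of 19 lower in B and 17 in A. Highest were Ido1 (111), Fcgbp, Ptn, the chitinase-like gene Chi3l1 and Ear11 in B. In A they were Fcgbp (276 against 3.64), Clic6, the proton pump gene Atp6v1b1 (277 against 6.76), Chi3l1 and Myh1. Ear11 has near-identical relatives and is uncertain. Counts were 2379 higher and 1317 lower in B, and 2263 and 1307 in A; without scaling they were 3796 and 637, and 3555 and 637. Hormone-sensing markers were 9 of 11 higher in B (median 2.37; Foxa1 3.71) and 8 in A (median 1.59). Luminal markers had medians of 0.36 and 0.44 and Kit ratios of 2.99 and 3.41. In the STAT3 and involution list Igfbp5 was 843 in B and 1214 in A against 73.8. Skeletal muscle markers were above wild type here too, 2.61 in B and 2.92 in A, with adipocyte medians of 1.89 and 1.94 and macrophage medians of 2.23 and 2.18. Fibroblast and matrix markers had medians of 2.10 and 1.87 (14 and 13 of 14 higher), endothelial markers 1.15 and 1.29 (8 and 9 of 11) and nerve markers 1.31 and 1.12.

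Both 2-allele genotypes were much closer to wild type at parturition, with 10 of 14 milk protein genes lower in BB and 9 in AB. Milk genes took 42.0% of FPKM in BB and 44.0% in AB, with list medians of −1.39 and −1.36. Csn2 was 110456 and 97643, and Lalba 7329 and 6598 against 10866. Csn1s2b was the exception in size, at 28.2 in BB and 284 in AB against 17144. Milk lipid genes remained lower, 14 of 19 in BB and 13 in AB, with the citrate carrier gene Slc25a1 at 93.9 and 111 against 846. Secretory pathway genes had medians of −0.05 and 0.09. Counts were 1054 higher and 702 lower in BB and 1334 and 712 in AB, and without scaling 1609 and 400, and 1770 and 438. Atp6v1b1, Clic6 and Chi3l1 were among the 5 highest in both, with Chi3l1 at 164 and 328 against 10.3. The lipocalin gene Apod (770.3 against 21.8) and Wisp2 joined them in BB, and Fcgbp and Igfbp5 (912 against 73.8) in AB. Muscle genes were below wild type, Tnnt3 and Ckm in both and Tnnc2 and Mylpf in AB, and the muscle list medians were −3.66 and −3.15 (12 of 14 lower in each). Ppapdc1a and the calcium pump gene Atp2b2 (1.25 against 63.3) were the other lowest genes in BB. All 14 fibroblast and matrix markers were higher in each, with medians of 2.21 and 2.31, and adipocyte markers had medians of 1.10 and 1.00. Macrophage markers had 1.43 and 1.44, endothelial markers 0.52 and 1.04, hormone-sensing markers 0.71 and 0.91 and brown adipocyte markers 0.22 and −1.08.

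At equal copy number, milk genes differed at parturition between the columns labelled A and B. In A, 9 of 14 milk protein genes were at least 2-fold higher, and none was lower. Glycam1 was 319 against 14.2, Wap 201 against 13.1, Csn1s2a 4152 against 345 and Spp1 405 against 39.6. Saa2, of the serum amyloid family and uncertain in level, was the fifth. Hormone-sensing markers were 4 of 11 lower in A, with the epidermal growth factor family gene Areg at 2.62 against 16.2 and the progesterone receptor gene Pgr at 2.10 against 8.67 (list median −0.68). Cell cycle genes had a median of −0.51. Across all genes only 47 were higher and 45 lower, or 40 and 28 with the floor of 5 FPKM, the lowest being Ido1 (1.03 against 111), Pcp4, Ear11, Col4a6 and Defb1. AB and BB differed in 139 higher and 94 lower genes, or 101 and 109 without scaling and 81 and 80 with the length and GC trend removed. Csn1s2b was highest in AB (284 against 28.2), followed by the angiotensinogen gene Agt, Ubd, B3gnt3 and Stat5a itself. Duoxa1, Ucp1, Atp13a4 and Gsta3 were among the lowest (−2.38 to −2.13), of which Gsta3 has close relatives. The milk list median was −0.12 (0.25 with the trend removed), 4 of 26 cell cycle genes were higher in AB (Mcm6 1.66), and interferon response genes had a median of −0.40. Endothelial markers had 0.51 and brown adipocyte markers −0.63.

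From 1 to 2 Stat5b alleles (BB against the column labelled B), the milk list median at parturition was larger than from 0 to 1. The step from 0 to 1 starts from the MMTV-Cre deletion of Null, so it is not one of copy number alone. How complete that deletion was cannot be told from these values. All 14 milk protein genes were higher in BB, by a median of 4.76. Glycam1 was 28455 against 14.2, Wap 17011 against 13.1, and Fabp3, Csn1s2a and Spp1 were next (log2 ratios 7.57 to 8.62). Elf5 was 725 against 126, but its STAT5-linked signalling list did not rise with it (mean log2 level 4.70 in BB and 4.81 in B). Hormone-sensing markers were 9 of 11 lower. The lowest genes were the muscle genes Acta1, Ckm, Tnnt3, Tnnc2 and Atp2a1, with Acta1 at 1.35 against 617 and a muscle list median of −6.75. The direction was opposite on day 6: the median level of the muscle list was 12.1 in BB and 2.85 in B there, and 0.448 and 179 at parturition. Muscle transcript thus did not follow Stat5b copies alike at the 2 stages. How much muscle the sampled tissue held is not known. Adipocyte markers had a median of −0.89 (7 of 18 lower), nerve markers −1.01 (3 of 6), macrophage markers −0.74 and endothelial markers −0.53. Counts were 424 higher and 603 lower, or 290 and 1023 without scaling. From 0 to 1 allele, milk list medians were 0.80 for the column labelled B and 2.45 for the column labelled A against Null. Btn1a1 was 149 in B and 209.8 in A against 5.46, Lalba 232 and 800.4 against 19.0, and the cholecystokinin gene Cck 43.8 and 69.7 against 1.56. Wap (13.1 in B) and Glycam1 (14.2) were lower than in Null (296 and 240.5). Other high genes were Saa3 in both, Tph1 and Pcp4 in B and Col9a1 in A. Other low genes were Tmem45b in both, the fibrinogen gene Fgg and Lgals12 in B, and Ido1, the muscle growth inhibitor gene Mstn, Defb1 and Gdpd3 in A. Luminal markers had medians of 0.75 and 0.77 and basal markers 0.81 and 0.74, while adipocyte markers had −0.77 and −0.88. Macrophage markers had 0.96 and 0.99, with 6 of 12 higher in each, and skeletal muscle markers −0.81 and −0.59. B differed from Null in 355 higher and 373 lower genes and A in 458 and 416, or 294 and 241, and 393 and 269, with the floor of 5 FPKM.

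The Null to wild-type ratio was then set side by side between the stages, as list means over genes tested in both tables, which were normalized separately. Milk protein genes had a mean log2 ratio of −3.08 on day 6 and −7.17 at parturition, and milk lipid genes −0.23 and −1.56. Secretory pathway genes had −0.15 and −1.14. Hormone-sensing markers stood at −0.50 and 1.69, fibroblast and matrix markers at −0.000296 and 2.27, and interferon response genes at −0.14 and 1.17. Other lists moved the same way: skeletal muscle 1.58 and 3.63, adipocyte 1.06 and 2.48, nerve −0.24 and 1.44, macrophage −0.27 and 1.05, and endothelial 0.37 and 1.51. Basal markers (0.28 and −0.25) and the STAT3 and involution list (0.15 and −0.61) moved the other way. Cell cycle genes, at −0.87 and −0.81, and luminal markers, at −0.50 and −0.38, differed little between the stages. No test of these stage differences could be made from means.

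**Figure D3:**
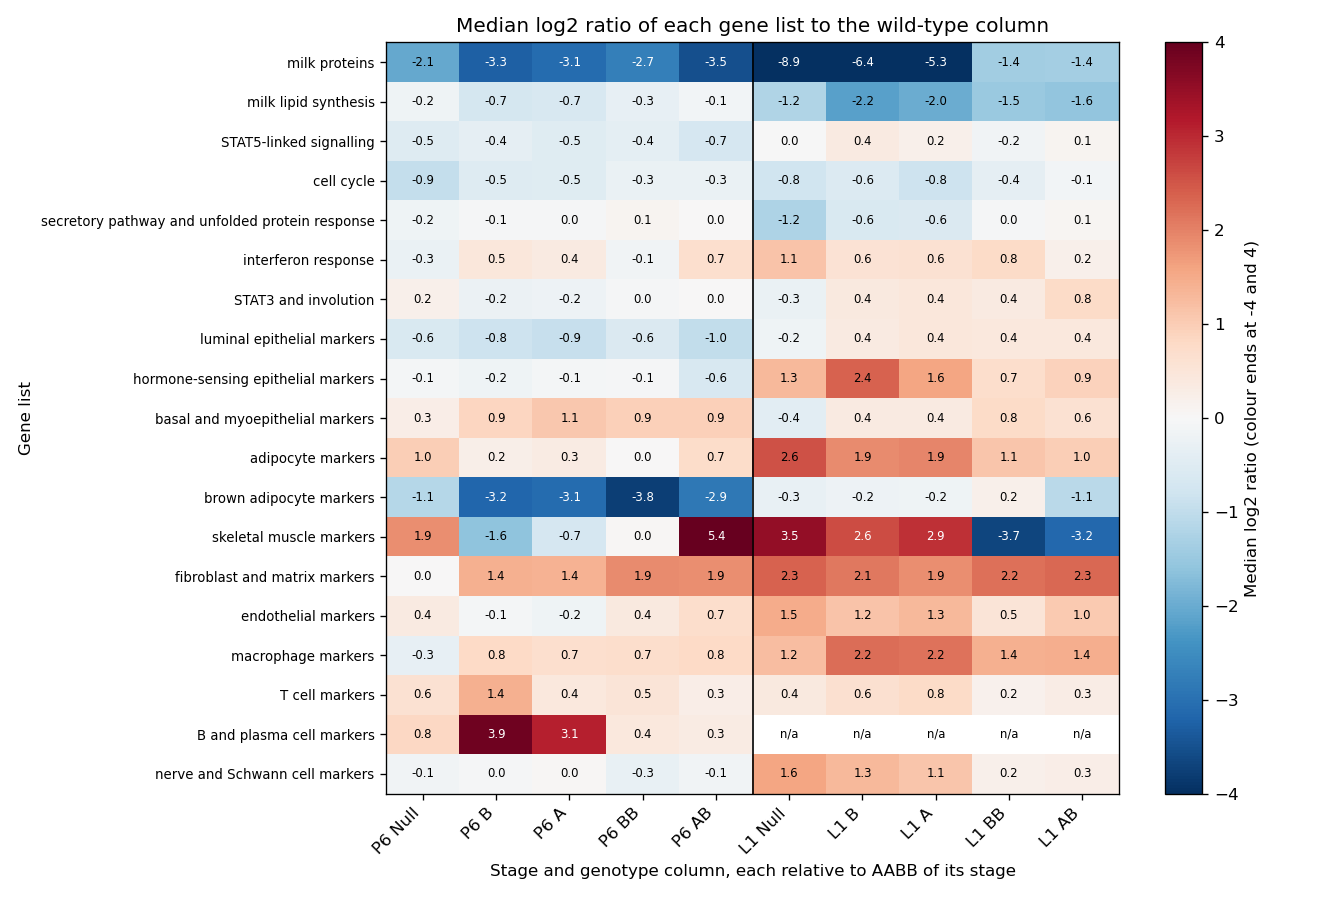
Median log2 ratio of each gene list to wild type (colour, ending at −4 and 4, with the value in each cell to 1 decimal), for the 5 other genotype columns at day 6 of pregnancy (P6) and parturition (L1); n/a marks lists with fewer than 3 measured genes. Milk proteins run from −8.92 in L1 Null to −1.36 in L1 AB, and skeletal muscle markers from −3.66 in L1 BB to 5.36 in P6 AB.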

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

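The tests with a floor of 5 FPKM and with the length and GC trend removed were chosen only after the data were seen. Among 370 list medians, 259 named gene ratios and 19 stage differences, none of at least 1 log2 unit changed sign under the alternatives that gave it a value. For named genes this was largely fixed in advance. A filter, a floor or a pseudocount cannot change the sign of a gene's ratio, and the scaling factors lie too close together to reverse a 2-fold ratio. Only removal of the length and GC trend could have reversed a named gene of that size. Of the smaller ones, 65 list medians, 2 named gene ratios and 1 stage difference changed sign in at least 1 alternative. The largest was the T cell median of A against wild type at parturition, 0.78 as reported and −0.32 without a filter on low values. Total counts of 2-fold genes stayed within 1.5 times the reported total in all 20 comparisons as deposited, without a filter, and with the trend removed, and in 18 of 20 with the floor of 5. There, day 6 of pregnancy (P6) gave 27 genes for A against B and 229 for AB against BB. With a pseudocount of 0.1, which by construction widens ratios of low values, all 20 totals were larger, 15 of them by more than 1.5 times. At P6 those 15 were 923 for Null, 2519 for A and 1891 for BB against wild type, 103 for A against B, 582 for AB against BB, 1432 for BB against B, and 2111 and 2214 for B and A against Null. At parturition (L1) they were 2818 for BB and 3136 for AB against wild type, 195 for A against B, 499 for AB against BB, 1699 for BB against B, and 1171 and 1383 for B and A against Null. This pseudocount also moved 79 of 259 named gene ratios and 12 of 370 list medians. Counts by direction moved further than totals. With the trend removed, lower genes were 384 (693 as reported) in P6 B and 385 (740) in P6 A against wild type and 349 (528) and 398 (624) against Null, higher genes 153 (250) in P6 BB against B and 81 (139) in L1 AB against BB. With the floor of 5, higher genes were 135 (231) in P6 AB against BB, and lower genes 14 (33) in P6 A against B, 377 (613) in P6 BB against B, 28 (45) in L1 A against B, and 241 (373) and 269 (416) in L1 B and A against Null. The floor only removes genes and leaves each ratio unchanged, so by construction its counts could only fall. The share of 2-fold genes that were higher depended on scaling: as deposited it was 40.0% (51.5% scaled) for P6 Null, 46.2% (58.7%) for BB and 40.4% (57.5%) for AB against wild type, 16.6% (29.0%) for BB against B, and 74.7% (61.9%) and 70.3% (56.6%) for B and A against Null. At L1 it was 82.7% (64.0%) for Null, 85.6% (64.4%) for B, 84.8% (63.4%) for A, 80.1% (60.0%) for BB and 80.2% (65.2%) for AB against wild type, 48.1% (59.7%) for AB against BB and 22.1% (41.3%) for BB against B. The median of all genes shifted without scaling by 0.40, 0.42, 0.40, 0.25 and 0.19 log2 for L1 Null, B, A, BB and AB against wild type and by −0.16 for L1 BB against B. At P6 it shifted by −0.10 and −0.15 for BB and AB against wild type, −0.14 for BB against B and 0.12 for B and for A against Null. With the trend removed, 70.4% (59.3% before) of the 2-fold genes were higher in P6 B and 66.9% (55.9%) in P6 A. The floor of 5 gave 48.1% (35.3%) for P6 A against B, and a pseudocount of 0.1 gave 41.0% (51.1%) for L1 A against B. The cause of these differences was not tested beyond what the alternatives themselves change. No paired analysis was possible because the tables hold 1 mean per genotype. For the same reason the replicate block, the block by shared sample tag, leaving out each replicate, estimated correlations for lists and permuted samples were not run. Since depth is unknown, genes of low FPKM have no stated precision.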

Other observations

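All tests in this part were chosen only after the result was seen, except the percent of genes kept after removal of the length and GC trend, and the genes named here were chosen after their values were seen. Of 12 circadian clock genes looked at on day 6 of pregnancy, after Dbp and Per3 had been seen, 9 had BB and AB both outside the range of the other 4 columns, 6 below and 3 above, and Nr1d1, Per1 and Cry1 did not. Dbp, an output gene of the clock, was 2.38 in BB and 5.00 in AB and between 22.6 and 45.6 in the other 4 columns. Per3 was 1.61 and 1.95 against 7.29 to 14.3, and Per2 1.51 and 1.26 against 5.14 to 13.2. Arntl, which encodes the activator BMAL1, was 10.6 and 10.5 against 1.85 to 4.88, and Npas2 4.01 and 3.85 against 0.656 to 1.60. At parturition 3 of these genes, Tef, Per2 and Per3, had BB and AB both below the others, and none had both above. The labels give no time of day for the tissue, and no explanation was tested.

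At parturition, wild type stood apart from the other 5 columns in 971 genes, 328 higher and 643 lower, and Null in 302, 196 higher and 106 lower. Sftpd, which encodes surfactant protein D, was 718 in wild type and at most 69.4 elsewhere. Egf was 34.5 against at most 3.04. The leptin gene Lep was 188 in Null and at most 29.5 in the others, while Cck was 1.56 in Null and at least 43.8 elsewhere.

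On day 6 of pregnancy the Null and AABB columns stood apart together from the other 4, with 36 genes higher and 204 lower by at least 2-fold, 240 in all, the most of the 31 ways to split the 6 columns. The split was picked because it separates the most genes. By that choice its genes are not ordered by copy number in the epithelium, so an effect of those copies was not tested on them. Null lost the genes in mammary epithelium only, so Null and AABB both keep the alleles in other cells. BB is a Stat5a knockout, and no such restriction is given for B, A or AB. Alleles lost outside the epithelium would therefore follow this split. After removal of the trend with length and GC content, 94.1% of the 239 genes with annotation kept a 2-fold difference of column means. The genes had been picked by a stricter gap between the columns, so most were likely to pass. Their median difference was 1.75 log2 before and 1.72 after, which argues against that trend as the whole cause for these genes. Over all genes the same difference correlated with length (Spearman −0.38) and with GC content (0.42). Of 14 fibroblast and matrix genes, 11 were higher in each of the other 4 columns than in both Null and AABB, so a larger stromal share in those tissues cannot be told apart from other sources, with fewer than the 12 genes it was taken to need. Alleles lost outside the epithelium, strain background, tissue sampling and library batch stay open and untested. The comparisons of B, A, BB and AB with AABB, and of B and A with Null, at this stage carry this pattern. That of Null with AABB does not.

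Milk protein genes at parturition were lower in Null, B and A than in AABB, with medians of −8.92, −6.39 and −5.26. An even loss of luminal cells would lower luminal markers alike, but the lowest median of the luminal list was −0.17, in Null. Its lower quartile there, −1.30, lay above the upper quartile of the milk list of −6.01, which argues against an even loss. The list does not set milk-secreting cells apart from other luminal cells, so a loss of milk-secreting cells alone stays open and untested. For milk transcripts filling the AABB libraries, each column was set relative to all other FPKM. That step shifts the ratios of a column almost alike, so medians of this size were bound to stay large. The median of smallest size, in A, was −5.00 after it and −5.26 before, which shows only that such filling moves these ratios little. A graded effect of copies above 1 is a candidate explanation, as 13 of 14 genes, Ltf excepted, lay lower in Null, B and A than in BB and AB and lower there than in AABB. The order was set after these values had been seen, so the count describes the pattern and gives no separate support. From 0 to 1 copy a graded effect stays open, since by any amount 9 of 14 genes were higher in B than in Null and 5 were lower, with 12 higher in A. Null also differs from B and A in the way the genes were lost.

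Stat5a transcript was present in the columns labelled B, which should lack functional Stat5a. An exchange of the A and B labels is argued against by Stat5a, of which the ratios of A to B lay above 0, at percentiles 98.7 and 99.5 of all genes. All 4 of 4 ratios of Stat5a and Stat5b had the labelled sign, but those of Stat5b (−0.20 and −0.27) lay at percentiles 8.60 and 6.24, within the spread of all genes, and add little. Whether cells with intact Stat5a in the tissue contribute stays open. Stat5a in B lay within 2-fold of Null, the epithelial deletion, at both stages (log2 ratios −0.11, of which the sign depends on scaling, and 0.27). At parturition it also lay within 2-fold of BB, the Stat5a knockout (0.86, against 1.53 on day 6), so the likeness to Null cannot decide. The genotype given for B, a single Stat5b allele, names no cells that keep Stat5a. Transcript of a disrupted allele also stays open and untested, since the labels do not say which transcript the Stat5ab-null and Stat5a knockout alleles leave.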
